A study of Mus musculus with 4 samples.

How the data were processed

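Tables of FPKM listed by RefSeq transcript accession were used for 4 RNA-seq libraries, 1 each for wild-type (WT) and Batf2-/- (KO) macrophages at 0 h and at 3 h of LPS. Per the labels, the libraries were strand-specific and read as single reads on an Illumina HiSeq instrument. The deposited values are FPKM with a lower and an upper limit and a status for each entry, as in a Cufflinks table. Per the submitters' processing notes, reads were aligned with TopHat2, which used Bowtie and SAMtools, to mm9, and FPKM was computed with Cufflinks. The versions are not given in the sources used here. The gene loci in the files fit GRCm38 (mm10) and not mm9: 95.8% of the entries lay inside the GRCm38 gene of their name, and 55.2% started at its exact start after 1 was added to the position, against 3.29% without. Coordinates are given as GRCm38/mm10 for this reason.

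Each library listed 33841 entries under 33324 RefSeq accessions. Of these, 33437 were named from the RefSeq accession in the gene table, 187 from the GENCODE RefSeq table and 73 by position, and 144 kept their accession. Il12b was among those named by position. The entries gave 24095 gene symbols or unnamed accessions, of which 5267 had over 1 entry and 276 lay at separate loci. FPKM of all entries of a symbol was summed when all were OK. Entries with a status other than OK numbered 435 (WT at 0 h), 413 (WT at 3 h), 428 (KO at 0 h) and 402 (KO at 3 h), and their 275 genes were left out of the comparisons that used that library. Values of 0 were kept, but a gene listed at 0 has no fold, and 138 genes had an FPKM of at least 5 in a library and 0 in another, 61 of them with a gene name. Eno1, Fdft1 and Ass1, which are list members, were listed at 0 in all 4 libraries. FPKM lay outside its own deposited interval for 1880, 1550, 2074 and 1886 entries in the same order, for a cause that was not tested. The ratio of FPKM to interval midpoint was mostly alike between libraries: for 88.2% of 8550 genes with a single entry it varied by under 5%. Intervals printed in the text were moved onto the FPKM with the same relative width.

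Depth was estimated from entries whose FPKM interval marks a single read and whose transcript is longer than 2000 bases in GENCODE. In units of 1000000 reads, the estimates were 24.8 (quartiles 24.1 and 25.4, WT at 0 h), 20.2 (19.5 and 21.0, WT at 3 h), 28.0 (27.3 and 28.9, KO at 0 h) and 30.7 (29.6 and 31.5, KO at 3 h), from 73, 83, 84 and 84 entries. Single-read entries shared with the WT library at 3 h gave relative depths of 1.22, 1.39 and 1.51 for the other libraries. The total FPKM was 466419, 469072, 476534 and 467189.

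Differences were computed as log2(FPKM + 1) of the first library minus the second, from the deposited FPKM without rescaling. With 1 library per group no test, p-value or standard error was computed. The size rule required a difference of at least 1 (2-fold), an FPKM of at least 1 in 1 or both libraries, the status OK in both, and deposited 95% intervals that do not overlap. The difference between LPS responses, (KO at 3 h minus KO at 0 h) minus (WT at 3 h minus WT at 0 h), required an absolute value of at least 1 and an interval, propagated from the deposited ones, that excludes 0. Overlaps were set beside the count expected for independent lists, the product of the list sizes over the number of genes tested in both. A total of 30 gene lists were written before the data were examined, as were the comparisons, the size rule and the rule for named genes. A list was summarised by the median over members with an FPKM of at least 1 in a compared library, when at least 3 were measured, and placed among the medians of 10000 random lists of the same size matched on expression in 20 bins. These placings describe these libraries and are not p-values. Named genes were Batf2, 18 key genes whatever their values, the 10 highest and the 10 lowest genes of each comparison with an FPKM of at least 5 that passed the size rule, without unnamed gene models, small RNAs and Batf2, and up to 4 or more members of each list. Some genes that this rule names are not reported here. Genes within 10 Mb of Batf2 were compared with random runs of as many detected genes on a chromosome.

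The rule was tested on simulated data of 24095 genes with counting error only. Changed genes were drawn from those with an FPKM of at least 2 in the second library, so recovery of lower genes was not tested. Of genes changed 3-fold, 94% to 96% were recovered in the 4 pairwise comparisons, and of those changed 4-fold 98% to 100%. Of those changed 1.5-fold 0% passed, and no unchanged gene did. Counting error alone could hardly bring such genes past a 2-fold rule. The simulation therefore does not show how often an unchanged gene passes between 2 cultures. Of 100 simulated lists of 12 unchanged genes, 6%, 10%, 9% and 5% fell outside the 2.5% limits at 0 h, at 3 h, after LPS in WT and after LPS in KO, where 5% is nominal. List placings near these limits are therefore less certain. Members of the simulated lists were drawn at random and varied independently, which members of a real list may not. The simulation thus does not show how often a real list falls outside these limits between 2 cultures alike in treatment and genotype. Alternatives tried were pseudocounts of 0.1 and 5, no filter on low values and a filter at an FPKM of 5, rescaling by the median ratio (factors 0.87, 1.13, 0.86 and 1.19) and to shares per total FPKM, no condition on the intervals, a 4-fold threshold and the omission of symbols at several loci. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Transcript forms were not analysed, since the entries of a gene were summed. Exon use and raw reads were not analysed either, since only these FPKM tables were at hand.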

Results

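RNA was sequenced from 4 mouse macrophage cultures, 1 library per culture, so that every group holds a single library. The cells were bone marrow-derived macrophages of C57BL/6 mice, grown for 6 days in medium with 10 ng/ml of the growth factor GM-CSF and collected as adherent cells. Cultures were either wild type (WT) or lacked Batf2 (Batf2-/-, called KO), a transcription factor of the basic leucine zipper family. Per the labels, all cultures received interferon-gamma at 10 ng/ml for 4 h and then lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, at 100 ng/ml for 0 or 3 h. Expression is given as FPKM, a read density that is scaled to transcript length and to the mapped reads of the library. In units of 1000000 reads, the libraries held an estimated 24.8 (WT at 0 h), 20.2 (WT at 3 h), 28.0 (KO at 0 h) and 30.7 (KO at 3 h) mapped reads. Genes with an FPKM of at least 1 numbered 10613, 9640, 10757 and 9557 in the same order. No group has replicates. No test was run for this reason, and the intervals given are the deposited 95% intervals, moved onto the FPKM with the same relative width, which cover counting and read assignment error of 1 library and not the spread between cultures. A gene is said to pass the size rule when log2(FPKM + 1) differed by at least 1 (2-fold), FPKM was at least 1 in a compared library and the intervals as deposited did not overlap. Differences below are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds, where given, are ratios of FPKM.

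Batf2 is the targeted gene and was examined first. It lies on chromosome 19 at 6164458 to 6172475 (GRCm38/mm10, forward strand), and its annotated principal transcript has 3 exons. In WT cells Batf2 had an FPKM of 2.63 (interval 1.86 to 3.39) at 0 h and of 234.3 (225.6 to 242.9) at 3 h, an 89.2-fold difference. In KO cells it had an FPKM of 0.26 (0.099 to 0.42) at 0 h and of 10.1 (8.89 to 11.3) at 3 h. Batf2 was thus 10.1-fold lower in KO than in WT at 0 h (interval 4.63 to 22.2) and 23.2-fold lower at 3 h (20.5 to 26.3). Reads assigned to the locus were still 38.9-fold more frequent at 3 h than at 0 h in the KO cells. The deleted part of the gene is not given in the labels, and values per exon were not analysed here.

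The first comparison asks how loss of Batf2 bears on the inflammatory transcriptome 3 h after LPS. Il23a, the p19 subunit that makes interleukin-23 together with the shared subunit p40, had an FPKM of 49.8 (46.7 to 52.8) in KO and of 10.6 (8.91 to 12.3) in WT, a 4.69-fold difference (3.94 to 5.58). Il23a lies on chromosome 10 at 128296140 to 128298084 (GRCm38/mm10, reverse strand). Il12b, which encodes p40, was 1.56-fold higher in KO (2916 against 1867 FPKM), with intervals that did not overlap, but stayed below the 2-fold size rule. Ebi3, a subunit of interleukin-27 and interleukin-35, was 1.45-fold higher (104.5 against 72.1 FPKM). Il12a, the p35 subunit of interleukin-12, differed by 1.13-fold (68.5 against 60.5 FPKM) and Il27 by 1.01-fold (368.7 against 364.3 FPKM). Of the 5 IL-12 family subunits, 1 passed the size rule as higher, and the median difference of 0.53 lay in the highest 2.5% of 10000 random lists matched on expression. All 5 were higher in KO.

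Of the 13 proinflammatory cytokines measured at 3 h, 12 were higher and 3 passed the size rule (Il23a, Lif and Csf3), with a median difference of 0.56, also in the highest 2.5%. Stromal markers lay in the highest 2.5% in the same comparison (5 of 5 higher, none past the rule, median 0.48). Lif, a cytokine of the IL-6 family, differed by 1.37 on the log2(FPKM + 1) scale and had an FPKM of 4.81 in WT. Il12b and Il23a belong to both the IL-12 family and the cytokine list. Csf3, the granulocyte growth factor G-CSF, had an FPKM of 6.11 against 2.01. Il1b, at 3976 against 2694 FPKM, and Il6, at 1052 against 826.5, differed by 0.56 and 0.35 and did not pass. Tnf (2815 against 2492 FPKM) differed by 0.18. Lta, lymphotoxin alpha, was the exception in direction, with 31.7 against 51.2 FPKM. Il10 was near the detection floor in both libraries, at 0.84 and 0.63 FPKM.

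Of 17 chemokines measured at 3 h, 13 were higher, with a median of 0.18 in the highest 2.5% of random lists, and Cxcl1, a neutrophil attractant, passed the size rule with 579.6 FPKM in KO and 245.6 in WT. Cxcl10 (1801 against 1945 FPKM), Ccl5 (4316 against 3287) and Ccl4 (1986 against 1224) did not pass. Cd14, a co-receptor for LPS, was the member of the Toll-like receptor list that passed, with 624.6 FPKM in KO and 294.4 in WT, and the list median was 0.02. No member of the following lists passed the size rule at 3 h, although some medians lay outside the middle of the random lists. In the highest 2.5% were the type I interferon-stimulated genes (median 0.19, 18 of 21 higher), the antioxidant genes (median 0.26, 7 of 7 higher), the feedback inhibitors of Toll-like receptor signalling (median 0.11, 12 of 14 higher) and the macrophage markers (median 0.13, 9 of 13 higher). Alternative activation lay in the lowest 2.5% (median -0.24, 9 of 12 lower). Between these limits were the interferon-gamma-induced GTPases (11 measured, median -0.14), MHC class II presentation (8 measured, median 0.09), MHC class I presentation (10 measured, median -0.13), the microbicidal effectors (12 measured, median 0.08), the NF-kappaB subunits (5 measured, median 0.16), the unfolded protein response (8 measured, median 0.08), the inflammasome (10 measured, median -0.04, turning positive with the median rescaling), glycolysis (12 measured, median -0.15) and cell cycle genes (16 measured, median -0.20). Nos2, the inducible nitric oxide synthase, had 340.8 FPKM in KO and 307.3 in WT, and Ifnb1, which encodes interferon-beta, had 20.6 and 19.5. The transcription factors Irf1 (370.4 against 419.3 FPKM), Irf8 (323.1 against 403.3), Batf (28.5 against 21.2) and Batf3 (7.44 against 10.6), which can share partners or sites with Batf2, did not pass. Within the list of 13 measured BATF, AP-1 and IRF factors (median -0.10), Fos was the only one besides Batf2 to pass. It was lower in KO by 1.05 on the log2(FPKM + 1) scale and had 6.27 FPKM in WT.

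**Figure D1:**
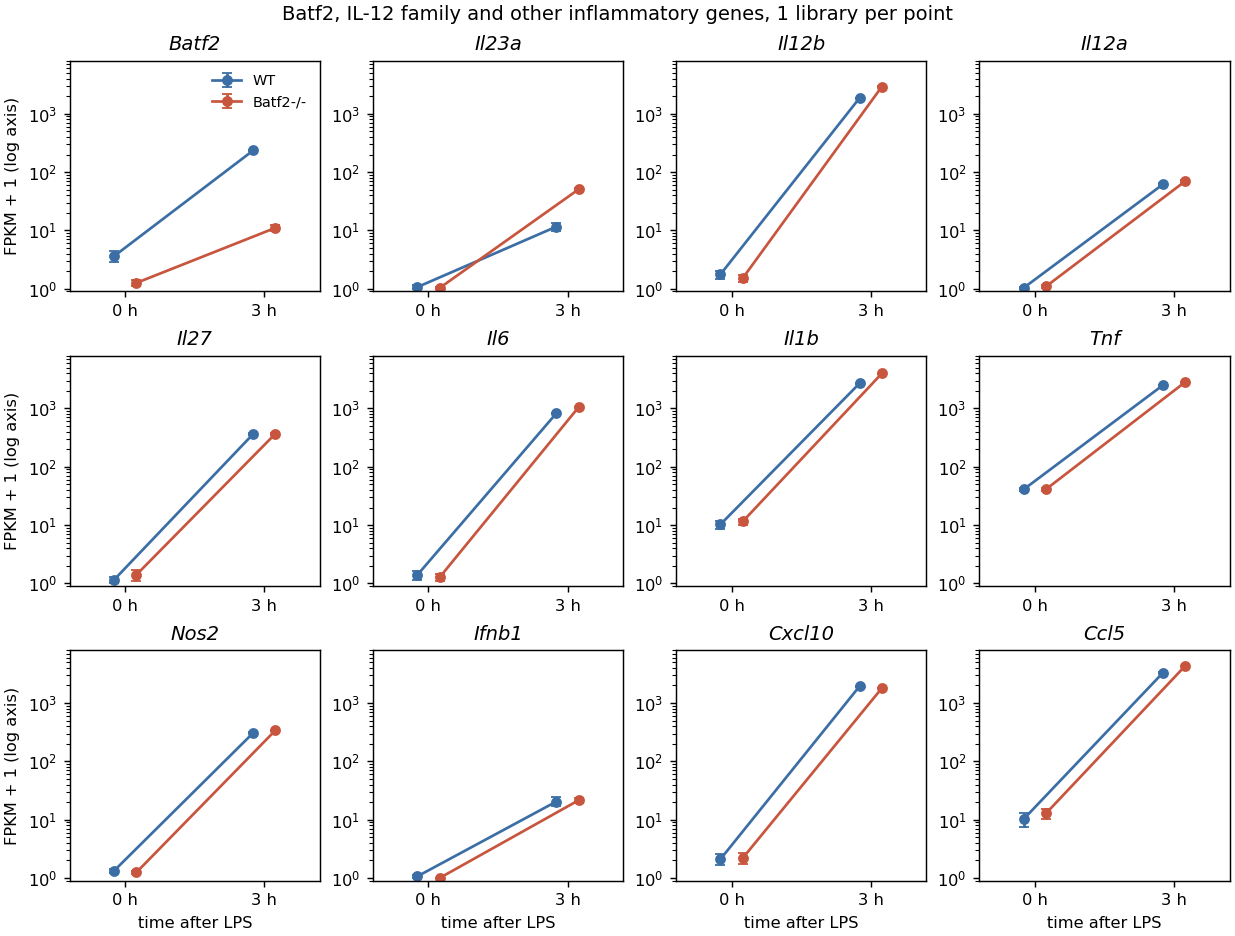
FPKM + 1 on a log axis for 12 genes at 0 h and 3 h after LPS, with 1 point per library, WT in blue and Batf2-/- in red, and error bars giving the deposited 95% interval moved onto the FPKM (counting error only). Batf2 reached 234.3 FPKM in WT and 10.1 in KO at 3 h, while Il23a reached 10.6 in WT and 49.8 in KO.

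Over all genes, 72 were higher and 68 lower in KO at 3 h among 9805 tested. Of these, 17 and 16 were listed at FPKM 0 in 1 of the libraries, where a failed estimate cannot be told from absence. Among named genes with a fold and an FPKM of at least 5, the highest differences were those of Ifi202b, a member of the interferon-inducible Ifi200 family (100.5 FPKM in KO, 0.029 in WT), Ctse, the aspartic protease cathepsin E (45.7 against 1.56), and Majin, a gene known from meiotic telomere attachment (6.91 against 0.20). Cxcl14, a chemokine, had 22.3 against 3.13 FPKM and Chil1, a chitinase-like glycoprotein, had 194.8 against 47.3. Besides Il23a, the other genes among the 10 highest were Adi1, U90926, Rps29 and Acpp, with differences from 1.51 for Acpp to 1.97 for Adi1. At the low end of the same genes, after Batf2 itself, stood F2rl2, the thrombin receptor PAR3 (0.27 FPKM in KO, 6.79 in WT), the lysosomal acetyltransferase Hgsnat (4.42 against 29.7), Timd4, a receptor for phosphatidylserine on apoptotic cells (1.73 against 11.9), Clec9a, a receptor for dead cells on dendritic cells (2.16 against 9.68), and F7, coagulation factor VII (25.5 against 75.6). Wdr92, Cyp4f18, B3gnt3, Eef1a2 and Emb completed the 10 lowest, with differences between -2.26 (Wdr92) and -1.41 (Emb). The calls for Cyp4f18 and B3gnt3 ended with a pseudocount of 5. Pdcd1lg2, which encodes the inhibitory ligand PD-L2, was the costimulatory list's 1 member past the rule, at 13.7 against 35.8 FPKM. All 14 measured genes of cholesterol biosynthesis were lower in KO, none past the size rule, with a median of -0.51 in the lowest 2.5% of random lists. Fcgr2b, the inhibitory Fc receptor, had 207.6 FPKM in KO and 74.8 in WT.

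The second comparison asks how the genotypes differed before LPS. At 0 h, 143 genes were higher and 41 lower in KO among 10842 tested, of which 14 and 12 were listed at 0 in 1 of the libraries. Markers of neutrophils and their precursors were higher in KO. All 11 measured members of that list went this way, 4 past the size rule, with a median of 0.97 in the highest 2.5% of random lists. The calprotectin subunits S100a8 (4545 FPKM in KO, 1838 in WT) and S100a9 (2481 against 1054), the granule protein Ltf (256.1 against 83.2) and Ngp (1129 against 391.9) passed. At 3 h the same list had a median of -0.00, a sign that turned with rescaling, and no member past the rule. All 6 measured stromal markers were also higher at 0 h (median 0.89), including Sparc (33.1 against 11.4 FPKM) and Col3a1 (2.30 against 0.38). The 7 measured markers of mast cells, basophils and eosinophils had a median of 0.45 at 0 h, and Hdc, the histidine decarboxylase that makes histamine, passed (3.86 against 1.26 FPKM). The macrophage list differed little (13 measured, median 0.11), with Apoe, apolipoprotein E, as its only member past the rule (663.1 against 311.5 FPKM).

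All 8 MHC class II genes were lower in KO at 0 h, none past the size rule, and their median of -0.76 lay in the lowest 2.5% of random lists. H2-Aa had 639.8 FPKM in KO and 1135 in WT, Cd74, the invariant chain, had 3810 and 6209, and Ciita, the class II transactivator, had 9.52 and 18.8. At 3 h these genes were close between the genotypes (Cd74 8213 against 7081 FPKM). The costimulatory list had a median of -0.41 at 0 h, with no member past the rule. Ccl22, a chemokine of dendritic cells and alternatively activated macrophages, passed the rule (149.0 against 302.3 FPKM), and Ccl17, a member of both the chemokine and the dendritic list, had 2553 against 4348 FPKM, a difference of -0.77. Dendritic cell markers had a median of -0.22 over 8 measured members, with Clec9a at 1.59 against 3.71 FPKM, and of -0.22 over 9 at 3 h. Fscn1, the actin-bundling protein fascin, went the other way (11.2 against 4.23 FPKM). The alternative activation list split, with Chil3 (438.7 against 179.7 FPKM) and Retnla (1.19 FPKM in KO, listed at 0 in WT) higher and Cd209a lower (2.13 against 6.46) past the rule, and a median of -0.03. All 14 measured cholesterol biosynthesis genes were lower (median -0.43), as at 3 h. Interferon-gamma-induced GTPases (9 measured, median -0.23), MHC class I genes (10 measured, median -0.15), cell cycle genes (16 measured, median -0.18) and the inflammasome (10 measured, median -0.15) lay in the lowest 2.5% of random lists, as did the costimulatory and dendritic lists. In the highest 2.5% were the chemokines (12 measured, median 0.29), the microbicidal effectors (11 measured, median 0.22), the proinflammatory cytokines (9 measured, median 0.17, a sign that turned without a filter on low values) and glycolysis (median 0.16, 12 of 12 higher). Between these limits were the antioxidant genes (7 measured, median 0.13), type I interferon-stimulated genes (17 measured, median -0.07), the Toll-like receptor pathway (16 measured, median -0.02), feedback inhibitors (13 measured, median 0.04), NF-kappaB subunits (5 measured, median -0.01), the BATF, AP-1 and IRF factors (13 measured, median -0.03) and the unfolded protein response (9 measured, median 0.01, a sign that turned with rescaling). More of the placed lists lay outside these limits at 0 h than between them, where 5% outside is nominal. A placing outside the limits thus does little to set a list apart in this comparison of single cultures.

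Among named genes with a fold and an FPKM of at least 5, those with the highest differences at 0 h included Ctse (21.4 against 1.22 FPKM), Arl9, Cxcl14 (21.1 against 2.41), Zfp971, Dpys, Stfa2, Chil1, Cxcl3 and Ifitm6. Stfa2, a cysteine protease inhibitor of the stefin family, had 151.4 FPKM in KO and 44.3 in WT. Cxcl3 and Ccl12 were the 2 members of the chemokine list higher past the rule, at 41.4 against 12.3 and 5.67 against 1.61 FPKM. Cxcl14 is not a member of that list. The lowest among these, besides Batf2, included Rmrp, Slc9a3r2, Rpph1, Spink2, Gvin1, Il1r1, Il1rl1, Mucl1 and F2rl2. Il1rl1, the interleukin-33 receptor, was 1.53 lower in KO, at 6.28 FPKM, and Il1r1, a receptor for interleukin-1, had 1.49 in KO and 6.34 in WT. The calls for Dpys, Slc9a3r2, Rpph1, Spink2 and Il1r1 ended with a pseudocount of 5. Tnf (40.0 against 39.9 FPKM), Il1b (10.5 against 9.27) and Ebi3 (38.2 against 34.5) were close at 0 h, and Il23a, Il12b, Il12a, Il27 and Il6 were all under 1 FPKM in both genotypes.

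**Figure D2:**
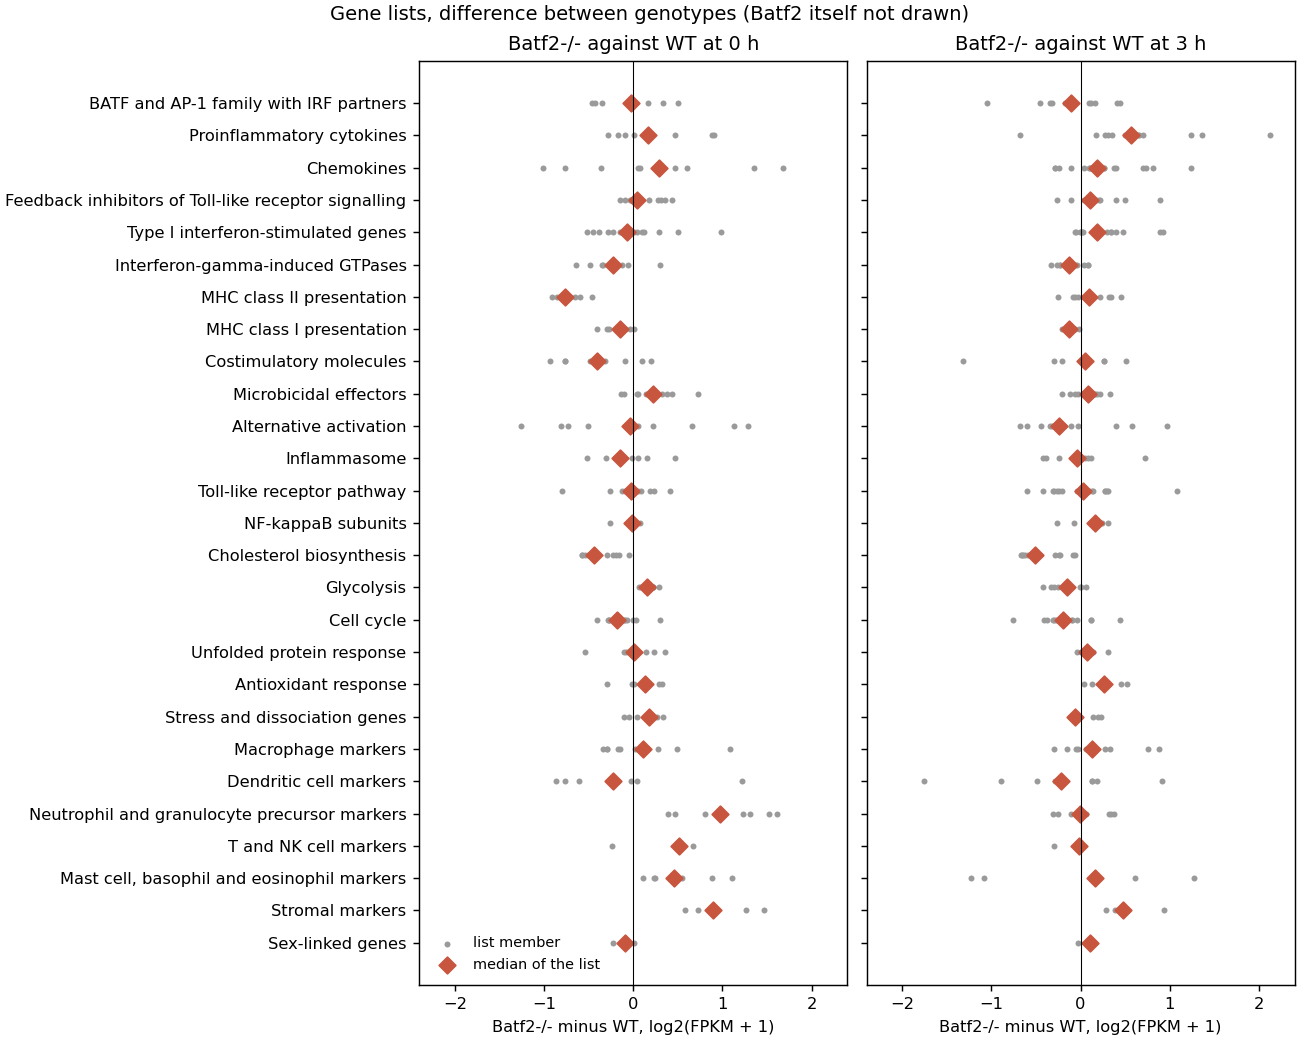
Difference between Batf2-/- and WT, in log2(FPKM + 1), for the members (grey dots) and median (red diamond) of gene lists, at 0 h on the left and 3 h on the right. Lists with at least 3 measured members at both times are drawn, which leaves out the IL-12 family. Batf2 is not drawn as a dot but counts in the median of its list. The neutrophil list has a median of 0.97 at 0 h and -0.00 at 3 h, the proinflammatory cytokine list has 0.17 and 0.56, and MHC class II has -0.76 and 0.09.

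The libraries at 3 h and 0 h of LPS were compared next in each genotype, and their difference is called the LPS response for short. Targets of interferon-gamma were low at 0 h, so that these differences cannot be assigned to LPS alone. In WT cells, 820 genes were higher and 2514 lower at 3 h than at 0 h among 10840 tested, and in KO cells 862 were higher and 3066 lower among 10961. The median difference of all tested genes was -0.54 in WT and -0.64 in KO, so that a share of the lower calls rests on the scale of the FPKM values. With the libraries rescaled by the median ratio the counts were 1106 higher and 1399 lower in WT and 1215 higher and 1491 lower in KO, and the share of higher calls moved from 24.6% to 44.2% in WT and from 21.9% to 44.9% in KO. Genes listed at 0 in 1 of the libraries made up 37 of the higher and 63 of the lower calls in WT, and 36 and 74 in KO. The differences that follow are as deposited, and each is to be read against these medians.

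Cytokine, chemokine and interferon genes were higher at 3 h in both genotypes. Il12b had the highest difference of all in both, at 10.05 in WT and 10.91 in KO. All 5 IL-12 family subunits passed the size rule in both genotypes (medians 5.89 and 5.99, Ebi3 in WT at 1.04 and at 0.96 with a pseudocount of 5), with Il23a moving from 0.066 to 10.6 FPKM in WT and from 0.029 to 49.8 in KO. Among 13 cytokines measured, 10 passed as higher in WT and 11 in KO (medians 3.45 and 3.51), including Il6 (differences of 9.22 and 9.70), Il1b (8.03 and 8.43) and Tnf (5.93 and 6.10). Of 17 chemokines, 13 and 14 passed as higher, with medians of 2.43 and 2.86, led by Cxcl10 (9.85 and 9.68), Cxcl9 (9.59 and 9.88) and Ccl5 (8.32 and 8.40). All 21 type I interferon-stimulated genes passed in both, with medians of 4.77 and 5.03, among them Oasl1 (8.20 and 8.40) and Rsad2 (7.50 and 8.42). All 11 interferon-gamma-induced GTPases passed, with medians of 5.50 and 5.14, as did all 5 NF-kappaB subunits, with medians of 2.23 and 2.55. Ptgs2, the prostaglandin synthase COX-2, had differences of 8.85 and 7.92, and Cd40, a costimulatory receptor, of 8.11 and 8.47. Nos2 had 7.85 and 8.10, and Il27 had 8.31 and 8.04. Of 14 feedback inhibitors of Toll-like receptor signalling, 12 passed as higher in each genotype, including Nfkbiz (6.28 and 6.36), with medians of 1.94 and 1.82. Irf1 (4.97 and 4.77) and Irf8 (4.31 and 4.01) passed as higher, Batf3 passed as lower (-1.80 and -1.79) and Batf did not pass (-0.07 and 0.37, the WT value turning positive with the median rescaling).

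Genes of antigen presentation, inflammasomes and microbial killing were higher in part. In MHC class I presentation 8 of 10 passed in both genotypes (medians 1.75 and 1.73). In MHC class II presentation none of 8 passed in WT (median 0.27) and 5 did in KO (median 1.21). The class II genes were lower in KO than in WT at 0 h (median -0.76) and close at 3 h (median 0.09). For the costimulatory list 8 of 9 passed in each genotype, for the inflammasome list 4 of 10, for the microbicidal effectors 6 of 12 and for the Toll-like receptor pathway 7 of 16 as higher, with 2 lower in WT and 3 in KO. Tlr4 itself had 31.8 FPKM at 0 h and 15.1 at 3 h in WT, and 30.7 and 12.6 in KO.

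Proliferation, sterol synthesis and alternative activation genes were lower at 3 h. Of 16 cell cycle genes, 14 passed as lower in WT and 13 in KO, with medians of -1.53 and -1.56, in the lowest 2.5% of random lists in both. Mki67 was the exception in direction, with differences of 0.19 and 0.73. Cholesterol biosynthesis had 8 of 14 and 9 of 14 genes past the rule as lower (both medians -1.23), among them Dhcr7 (-2.78 and -2.81) and Sqle (-1.80 and -2.05). In the alternative activation list 7 of 12 were lower in WT and 6 of 13 in KO, including the transcription factor Klf4 (-3.60 and -3.69) and the mannose receptor Mrc1 (-1.95 and -2.00), while Tgm2 (2.45 and 2.20) and Ccl24 (1.45 and 1.82) were higher. In the antioxidant list (medians -0.15, turning positive with the median rescaling, and 0.33), Slc7a11 (2.04 and 2.39) and Txnrd1 (1.33 and 1.50) were higher and Gclc was lower (-1.26 and -1.23). Xbp1, a transcription factor of the unfolded protein response (medians -0.58 and -0.57), was lower (-1.52 and -1.29). The glycolysis list had 1 member past the rule in each genotype, Hk2 (1.27 and 1.22), and its medians of -0.16 and -0.46 turned positive with the median rescaling. Among macrophage markers (medians -0.32 and -0.29, both turning positive with the median rescaling) Mertk (1.40 and 1.60) was higher. In each genotype 1 macrophage marker passed as lower, and the lowest difference in the list was -3.38 in WT and -3.07 in KO. Among dendritic cell markers the chemokine receptor Ccr7 (2.78 and 3.65) and Xcr1 (2.08 and 1.73) were higher and Kmo (-1.48 and -1.51) was lower. Among named genes with a fold and an FPKM of at least 5, the lowest differences in WT were those of Galnt9, Zfp36l2, Lhfpl2, Dhrs3, Eps8, Rab3il1, Klf4, Cd300lb, Zfp703 and Pald1, from -4.37 (Galnt9) to -3.44 (Pald1). In KO the lowest among such genes were those of Cd300lb, Lhfpl2, Dhrs3, Galnt9, Eps8, Arhgap25, Klf4, Tmem86a, Emp1 and Rab3il1, from -4.39 (Cd300lb) to -3.60 (Rab3il1).

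The LPS responses of the genotypes followed each other closely across genes. Among 10659 genes tested in both, 721 were higher in both and 2207 lower in both, where independent lists of these sizes would share 63.4 and 709.9. Pearson's r of the differences was 0.92 and Spearman's rho 0.92 across genes, which are not independent replicates. Only 2 genes, Akr1b3 and Capzb, passed in opposite directions, and both were listed at 0 in a compared library.

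**Figure D3:**
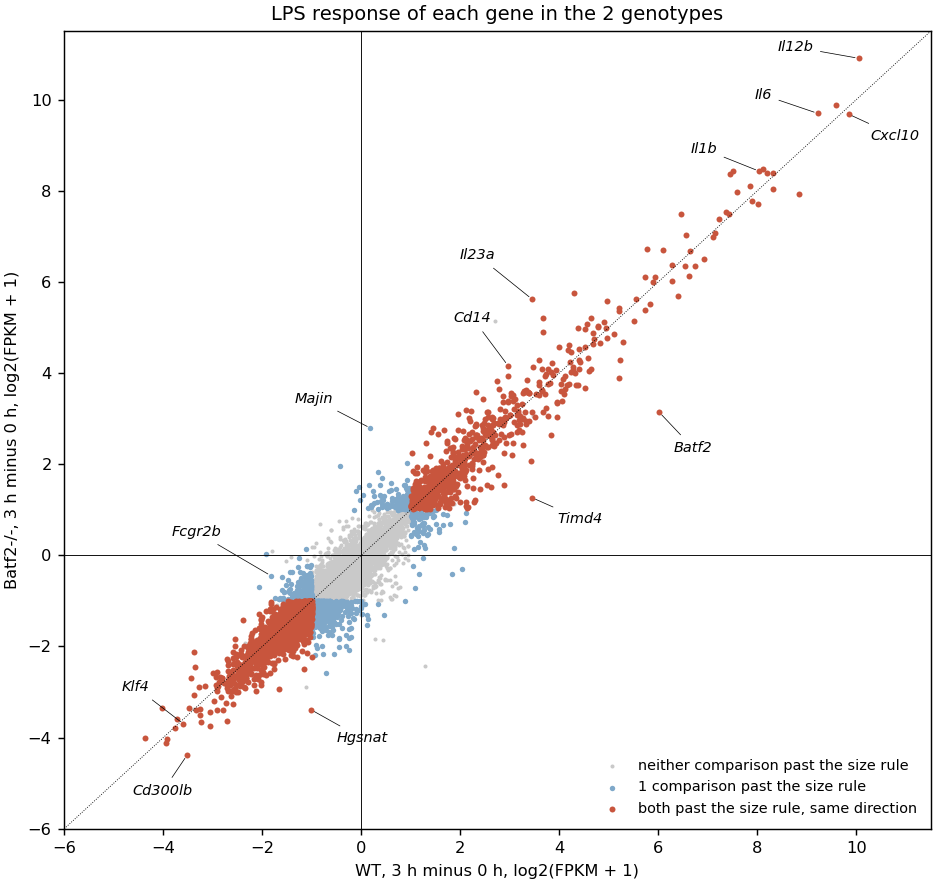
Difference between 3 h and 0 h of LPS in log2(FPKM + 1) for each gene with an FPKM above 0 in all 4 libraries and of at least 1 in any, WT on the x axis and Batf2-/- on the y axis, coloured by whether the gene passed the size rule in both genotypes, 1 or neither, with the dotted line marking equal differences. Most genes lie along the line (r = 0.92 over all genes tested in both), Il23a and Majin lie above it and Batf2, Timd4 and Hgsnat below.

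The difference between the LPS responses, KO minus WT, passed the size rule as higher in 104 genes and as lower in 168 among 11123 tested. Genes listed at 0 in a library supplied 54 and 64 of these calls, and without them the counts were 50 and 104. After Majin (2.61), Il23a had the highest difference among named genes with a fold and an FPKM of at least 5 (2.18, with a propagated half-width of 0.25). Adi1, Mucl1, Nr4a3, Rps29, the complement factor Cfb, Olfr110 and Fcgr2b were among those that followed, from 1.97 (Adi1) to 1.37 (Fcgr2b). Mucl1 and Cfb passed as lower in KO at 0 h and did not pass at 3 h. Ifi202b passed as well but has no fold, since it was listed at 0 in WT at 0 h. Csf3 (1.30), Cd14 (1.20), Ccl22 (1.13) and Tnfsf15 (1.02) also passed, as did the class II genes H2-Aa (1.17), H2-Ab1 (1.18) and H2-Eb1 (1.27). Ccl22 and the class II genes were lower in KO at 0 h, and the class II list was close between genotypes at 3 h (median 0.09). Il12b had a difference of 0.86, which passed with a pseudocount of 0.1 (1.13), and Il6 had 0.48, Il1b 0.40, Tnf 0.17, Il12a 0.10, a sign that turned with a pseudocount of 0.1, and Il27 -0.27. Among named genes with a fold and an FPKM of at least 5, the lowest values after that of Batf2 (-2.88) were those of Hgsnat (-2.38), Wdr92 (-2.26), Timd4 (-2.19), Hmga2-ps1, Cyp4f18, Vsig8, Epx, Lcn2, Csta2 and Ltf (-1.61). The calls for Olfr110, Cyp4f18 and Epx ended with a pseudocount of 5. Of the 11 neutrophil markers measured, 6 passed as lower and none as higher, with a median of -1.02, since these markers were higher in KO at 0 h and close at 3 h. No member of the type I interferon list (median 0.22), the GTPase list (median 0.09) or the NF-kappaB subunits (median 0.17) passed.

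Genes that differed between genotypes at both times were counted last. Among 9506 genes tested at both times, 20 were higher in KO at both and 7 lower at both, where independent lists would share 0.62 and 0.22. Pearson's r across these genes was 0.26 and Spearman's rho 0.27. Without the 3 genes listed at 0 the shared genes numbered 19 higher and 5 lower. The higher ones included Ctse, Cxcl14, Chil1, Nectin3 (2.77 against 0.099 FPKM at 0 h and 3.75 against 0.20 at 3 h), Tnfaip1, the collagen crosslinking enzyme Lox (15.6 against 4.77 and 13.6 against 5.64), the platelet chemokine Pf4 (259.7 against 121.3 and 281.6 against 108.4) and the haem synthesis enzyme Alas1 (498.9 against 227.2 and 466.1 against 229.1). The lower ones were Batf2, Hebp2, F2rl2, the fatty acid desaturase Scd1 (8.14 against 19.7 and 2.01 against 5.58) and Eef1a2 (27.2 against 65.5 and 11.9 against 34.8). The 3 genes that passed in opposite directions at the 2 times, Plpp1, Capzb and Akr1b3, were all listed at 0 in a compared library. Within 10 Mb of Batf2, none of 211 detected genes passed the rule the same way at both times, and the median of random runs was also 0. The median absolute difference of these genes was 0.14, at the percentile of 57.9 among random runs of as many neighbouring genes.

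**Figure D4:**
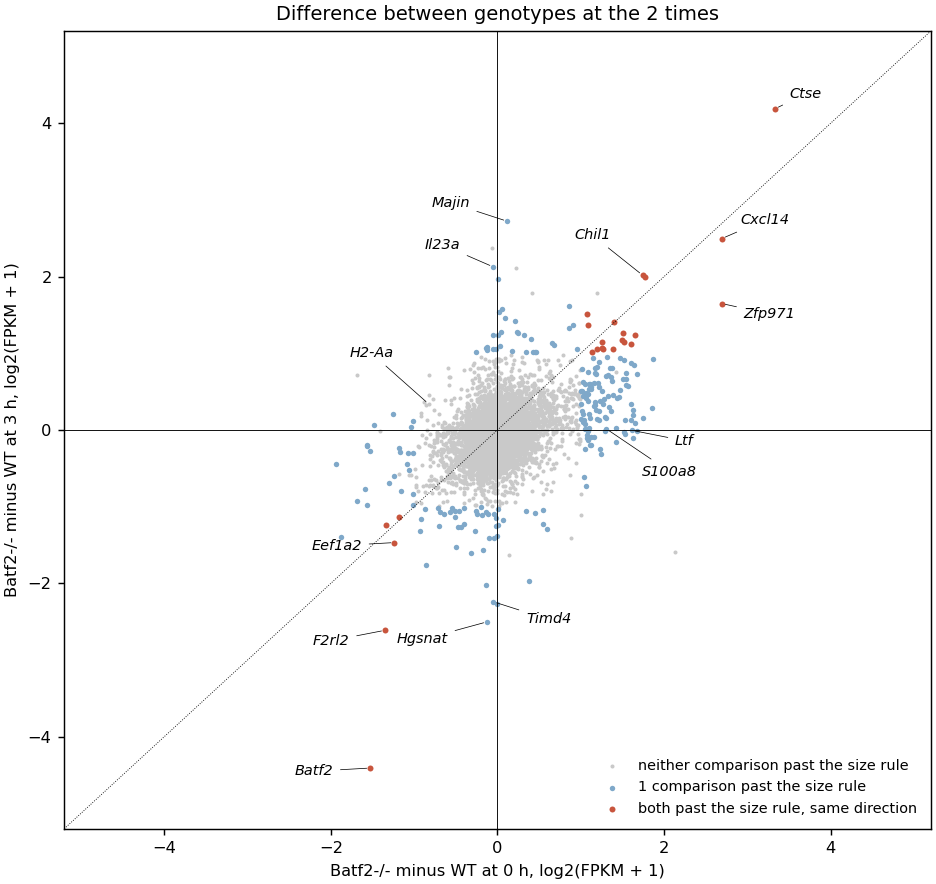
Difference between Batf2-/- and WT in log2(FPKM + 1) at 0 h (x axis) and 3 h (y axis) for each gene with an FPKM above 0 in all 4 libraries and of at least 1 in any, coloured by whether the size rule was passed at both times, 1 or neither. Ctse, Cxcl14 and Chil1 are higher and Batf2, F2rl2 and Eef1a2 lower at both times, Il23a differs at 3 h only, and Ltf and S100a8 differ at 0 h only.

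No B cell marker (7 listed) and no erythroid marker (6 listed) reached an FPKM of 1 in any library, the highest values being 0.61 for Cd79b and 0.47 for Hba-a1. Of the T and NK cell markers 3 were measured in each comparison of genotypes, with Cd4 the highest at 4.50 FPKM in WT at 0 h, and none passed the rule. Of the sex-linked genes, the 4 Y-linked ones were measured in all libraries (Ddx3y 14.2 FPKM in WT and 14.3 in KO at 0 h), none passed, and Xist stayed at or under 0.0057 FPKM. For mast cells, basophils and eosinophils at 3 h, Gata2 passed as higher (2.24 against 0.34 FPKM) and Prg2 (11.1 against 24.6) and Epx (1.75 against 5.45) as lower. The stress and dissociation genes (7 measured) had no member past the rule between genotypes at either time, with a median of 0.18 at 0 h, in the highest 2.5% of random lists, and of -0.06 at 3 h, a sign that turned with the median rescaling.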

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

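Most results kept their direction and their side of the size rule. For genes, 1153 of 1168 values under alternatives stayed on the same side of the size rule, 12 lost the call (all with a pseudocount of 5) and 3 gained one. The filters on low values and the omission of symbols at several loci cannot change the difference of a gene. Agreement was therefore fixed in advance for the values without a filter (176), with the filter at 5 (163) and without such symbols (164). Only the pseudocounts and the rescalings could move a gene. The sign changed for 6 of the 1168 values, none of them past the rule in the main analysis. For gene lists, 914 of 962 medians stayed on the same side of the 2.5% limits, 15 came to lie between them and 29 outside, and 4 medians outside the limits changed sign. A further 34 medians between the limits changed sign. Batf2 at 0 h differed by -0.54 with a pseudocount of 5, below the size rule, because the larger pseudocount shrinks differences of low genes. The counts of genes depended more on the processing, and unless stated the cause was not tested. With a pseudocount of 0.1, 271 genes were higher and 76 lower in KO at 0 h, 133 and 142 at 3 h, 175 and 325 for the difference of LPS responses, and 60 genes differed the same way at both times. With a pseudocount of 5 these were 48 and 15, 27 and 18, 58 and 80, and 9, while 790 genes were lower after LPS in WT and 959 in KO, and 1203 responded the same way in both genotypes. With the FPKM filter at 5, which tests fewer genes, 87 genes were higher at 0 h, 46 higher and 41 lower at 3 h, and 14 differed the same way at both times. With FPKM as shares of the total, 68 genes were lower at 0 h, 110 were higher and 107 lower at 3 h, and 47 differed the same way at both times; this scale roughly doubles the values, which makes the pseudocount of 1 weigh less. With the median ratio, 1399 genes were lower after LPS in WT and 1491 in KO. With the 4-fold threshold, stricter by construction, 11 genes were higher and 10 lower at 0 h, 15 and 14 at 3 h, 364 and 294 after LPS in WT, 366 and 365 after LPS in KO, and 45 and 54 for the difference of responses, with 5 the same way at both times and 560 responding the same way in both genotypes. Without genes listed at 0, the difference of responses had 50 and 104 genes. Proinflammatory cytokines at 0 h turned from a median of 0.17 to -0.051 without a filter on low values, and dendritic cell markers after LPS in WT turned from 0.04 to -0.086 with a pseudocount of 5, -0.10 without a filter and -0.30 with the filter at 5; the cause was not tested. Omitting the interval condition, leaving out symbols at several loci, moving the intervals onto the FPKM and a window of 5 Mb around Batf2 moved no count by over 1.5 times. The alternatives that left out genes listed at 0 and that moved the intervals were chosen after the data were seen. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers, with 1 library each, and no replicate could be left out. An additive fit of genotype and time, whose 1 residual degree of freedom holds any difference between the LPS responses, was not run. Depth was lowest in WT at 3 h, at an estimated 20.2 x 1000000 reads, which widens the intervals of low genes there.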

Other observations

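The genes in this paragraph passed the size rule at 3 h and were picked after the data were seen. Il7r, a cytokine receptor chain, had 79.8 FPKM in KO and 38.7 in WT, Trem1, an activating receptor of myeloid cells, had 12.7 and 5.72, Timp1, a protease inhibitor, had 203.1 and 94.0, and Cst7, a cystatin, had 60.2 and 26.9. Lower in KO were Cd226 (9.17 against 23.3 FPKM), Cd200 (17.1 against 37.6), the nuclear receptor Vdr (1.88 against 5.74), the lipid transporter Abcg1 (8.68 against 19.8), the nuclease Dnase1l3 (3.26 against 10.3) and Fgl2 (65.1 against 136.0).

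Ifi202b and Majin stood out in 1 library only. Ifi202b had 100.5 FPKM in KO at 3 h and at most 0.029 in the other libraries, while 10 neighbours of the same Ifi200 family on chromosome 1 had differences from -0.63 to -0.01 at 3 h and none passed the size rule. Majin had 6.91 FPKM in KO at 3 h and at most 0.20 in the others, and its locus starts 11.9 kb downstream of Batf2 on the same strand. All 8 stefin genes of a cluster on chromosome 16 were higher in KO at 0 h (median difference 1.44), and none passed at 3 h (median 0.21).

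Neutrophil markers were higher in KO at 0 h, and 2 explanations by cell composition were tested. For a larger share of granulocytic cells in the KO culture, 12 further granulocyte genes, among them Lcn2 and Cd177, were chosen after the marker result and before their own values were seen. Their median difference was 1.07 at 0 h, with 8 of 12 past the rule as higher, and -0.10 at 3 h, with 1 of 11. A larger share of granulocytic cells in the KO culture at 0 h would give the difference at 0 h. The values are averages over a culture, so that a larger share of such cells cannot be told from higher expression per cell. A lower share of macrophages in the KO culture, a test chosen after the result was seen, would raise all lists of other cells. The neutrophil, stromal and mast cell lists had medians of 0.97, 0.89 and 0.45, and the dendritic cell list, whose members went both ways, had -0.22. The macrophage list itself was not lower in KO at 0 h (median 0.11, 8 members higher and 5 lower). With 1 culture per group, this explanation was left open. With 1 culture per group, an effect of Batf2 on these cells cannot be told from a chance difference between cultures.

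Genes that differed between KO and WT at both times may come from donors or from DNA of another strain, and the predictions on strain DNA around the targeted locus and on donors of different sex were written before the data were examined. Of 211 genes near Batf2, 0 differed the same way at both times, but the median of random runs was also 0, so this test could not exclude strain DNA there. The largest difference of a sex-linked gene was 0.23, which does not support donors of different sex. For DNA of another strain outside the Batf2 region, a test chosen after the result was seen, 3 of 23 genes had another one within 1 Mb, a count at the percentile of 92.7 among random draws. The 3 were Gm14325, Gm14326 and Zfp971, and without zinc finger genes the count was 0 of 20, so the test could not tell. It does not count genes farther apart than 1 Mb, such as Ctse and Chil1, which both lie on chromosome 1. Genes that differed at 1 time only, such as Ifi202b, were not part of it.

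Interferon-gamma-induced genes were low at 0 h although the labels give 4 h of interferon-gamma to all cultures. In WT at 0 h Cxcl9 had 0.62 FPKM, Gbp5 3.52, Iigp1 0.12 and Irf1 12.4. The median over 11 GTPases of FPKM at 0 h was 1.85% of that at 3 h in WT and 2.22% in KO, in a test chosen after the result was seen. For the explanation that the 0 h libraries hold no response to interferon-gamma, the test could not tell, since no library without interferon-gamma was analysed here. The differences between 3 h and 0 h may therefore include the response to interferon-gamma beside that to LPS.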
